A study of Rattus norvegicus with 8 samples.

How the data were processed

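RNA was measured in 8 isolated rat hearts, each hybridized to its own Affymetrix array. Per the labels' protocols, hearts of male Wistar rats were perfused for 2 h in a non-recirculating Langendorff apparatus, in which the coronary vessels of an excised heart are fed through the aorta. The perfusate held either no drug (4 control hearts) or doxorubicin (4 hearts). The dose is taken as 2 µM, since the character before the molar sign is lost in the label. Doxorubicin is an anthracycline, a DNA-intercalating anticancer drug that poisons topoisomerase II. The labels call the 4 hearts of a group biological replicates, and each was treated as a separate animal. Total RNA was extracted on spin columns and turned into biotin-labelled cRNA, per the labels' protocols.

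The values in the deposited table are probe set intensity values that the authors made with RMA (robust multi-array average, which corrects background, normalizes the arrays together and summarizes the probes of a probe set), per the submitters' processing notes. The RMA software, its version and the probe set definitions are not given in the sources used here. RMA commonly returns log2 values, but the deposited intensity values were on a linear scale, with array medians of 29.9 to 31.0 and array maxima of 21852 to 23267. The log2 of each value was therefore taken before any test, with no offset. RMA makes the overall distributions of arrays alike, so a change shared by most transcripts would not show in these values. The deposited values carry no detection calls. The dimmest 25% of probe sets have a mean under 4.16 log2, and folds that involve such a group mean are uncertain. Arrays have no sequencing depth, so the number of arrays limits the precision.

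The table held 31099 probe sets, of which 57 were AFFX controls, leaving 31042 for testing. Gene symbols came from the platform annotation and were updated through the gene ID in the RefSeq table of the GRCr8 assembly, which was used only for names. A single symbol was given for 20826 probe sets, several for 436 and none for 9780. Of the 20826, the gene ID of 20758 was found in the RefSeq table and that of 68 was not. No gene was named from a probe set with several symbols. Each of 14217 genes was represented by its probe set with the highest mean over all 8 arrays, and the other probe sets of a named gene were read for disagreement. Genome positions were not used here, because the build of the array design was not given in the sources used here.

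Doxorubicin was compared with control by limma 3.58.1 in R 4.3.3, with lmFit and eBayes on log2 values over all 8 arrays and no covariate. Adjusted p-values are Benjamini-Hochberg values over the 31042 probe sets unless stated otherwise, two-sided, and a probe set or gene was called changed under 0.05. Differences are doxorubicin minus control on the log2 scale, with the standard error (SE) of the limma fit, and levels are group means with the standard deviation (SD) over 4 arrays. In total, 39 gene lists for pathways and cell types were tested with camera, a test of whether the genes of a list differ more than other genes, at a preset correlation of 0.01 between genes. Its p-values were adjusted over the 39 lists. An estimated correlation and fry, which tests whether the genes of a list move one way on balance, were run beside it. The lists named 1064 members counted per list, of which 999 were measured and the other 65 are not analysed here. Array quality values were compared with exact permutation tests over the 70 ways of drawing 4 of 8 arrays, whose smallest two-sided p is 0.0286. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

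The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. Named were the 12 genes with the highest and the 12 with the lowest log2 difference among called genes, leaving out symbols that are only locus numbers. From each list up to 4 members were named, called ones with the smallest p first, then those with the smallest p. Other called list members named in the text were chosen after their values were seen. The design allowed for log2 or linear values, and log2 was taken once the values were seen to be linear.

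The script was tested on simulated data for the comparison of doxorubicin with control over 31042 probe sets, with 200 of them changed. It recovered 92 of 100 probe sets changed by 2-fold and 76 of 100 changed by 1.5-fold, all with the right sign, with 14 false calls. In simulations of the 39 lists over 14217 genes, camera called 0 lists where none was changed, and 1 where immediate early genes were lowered. The simulated genes varied independently of each other, so this says nothing of false calls where the genes of a list vary together.

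Alternatives fixed beforehand were a repeated quantile normalization, median centring, a filter on dim probe sets, an intensity trend or robust fit in eBayes, array weights, the mean of the probe sets of a gene, adjustment over genes alone, the replicate number as a block, an offset of 16 before log2, and leaving out each array in turn. Covariates for the hybridization control level and for the atrial marker level (mean log2 of Myl4 and Myl7) were added after seeing the data. Of the 31042 probe sets, the 9780 without a symbol and the 436 with several entered the counts of probe sets but no count of genes.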

Results

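The array data covered hearts perfused for 2 h without drug (n = 4) or with 2 µM doxorubicin (n = 4), and the comparison asks which transcripts of the isolated heart differ after this short exposure. Between arrays of one group the correlation over all probe sets was 0.988 to 0.996, and between arrays of different groups 0.985 to 0.993, both across probe sets, which are not independent replicates. None of the 28 pairs of arrays held identical values. The first principal component took 37.3% of the variance and separated the groups, with control hearts at -30.5 to -1.40 and doxorubicin hearts at 12.3 to 21.2. The hybridization control level is the mean of 18 probe sets, which read bacterial and phage transcripts added to the labelled sample. It was 10.32 ± 0.17 log2 in control and 10.02 ± 0.08 log2 in doxorubicin arrays (SD, n = 4). The difference was -0.30 (exact permutation p = 0.0286, the smallest possible, adjusted p = 0.1 over 7 quality measures). All 18 probe sets were lower on the doxorubicin arrays, but several of them read the same transcript. The 3′ to 5′ difference of the GAPDH control was 0.19 ± 0.07 and 0.18 ± 0.01 log2 (SD, n = 4; exact permutation p = 0.8).

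Doxorubicin hearts had lower levels of 22 of 35 measured immediate early genes, which cells switch on within minutes of a stimulus, and of 14 of 30 NF-kB and cytokine genes. The transcription factor Atf3 was 3.84-fold lower (log2 difference -1.94, SE 0.13, n = 4 and 4), the chemokine Ccl3 3.47-fold lower (-1.79, SE 0.13) and the growth-arrest gene Gadd45g 10.8-fold lower (-3.43, SE 0.20). Far fewer transcripts rose by as much, and Fam111a, which encodes a serine protease, rose most, 64.1-fold (SE 0.65 on the log2 scale), with control 2 apart from the other control hearts. In all, 422 of 14217 genes changed at a limma adjusted p under 0.05, of which 308 fell and 114 rose. Among the 233 that changed by at least 1.5-fold, 194 fell and 39 rose, and among the 90 that changed by at least 2-fold, 83 fell and 7 rose.

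By probe set, 687 of 31042 changed, 473 downward and 214 upward. No gene symbol was given for 121 of the 687. At an unadjusted p under 0.05 the balance was different, with 2400 probe sets higher and 1814 lower of 4214. The median difference over all probe sets was near 0 (-0.0019 log2). The gene count was 267 without control 3 and 248, 278 and 262 without doxorubicin 1, 2 and 3. Without control 2, 215 genes rose against 114 with all arrays, and without doxorubicin 1, 44 did. With the hybridization control level as a covariate, added after seeing the data, 60 genes were called, 57 of them lower.

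The 12 genes with the steepest falls included regulators of transcription and genes of muscle structure. After Gadd45g came Klhl40, a stabilizer of muscle thin filaments (-3.33, SE 0.19), and H4cl1, a histone H4 gene (-3.02, SE 0.14), whose doxorubicin mean lay under 4.16 log2, the level under which the dimmest 25% of probe sets lie, so its fold is uncertain. Nr4a3, an orphan nuclear receptor, fell by 2.78 (SE 0.25). A second Nr4a3 probe set also fell, by 2.62, while the remaining one stood at 0.31. Further falls were seen for the LIM-domain cofactor Lmcd1 (-2.70, SE 0.13), for Ppp1r10, a nuclear subunit of protein phosphatase 1 (-2.52, SE 0.20), and for Mustn1 (-2.47, SE 0.16). Abra, which encodes an actin-binding protein of striated muscle, fell by 2.22 (SE 0.20) and Xirp1, which encodes the actin-binding protein Xin, by 2.07 (SE 0.19). The endothelial adhesion molecule Sele fell by 2.06 (SE 0.18), Bcr by 2.02 (SE 0.13) and Irs2, an adaptor of the insulin receptor, by 2.01 (SE 0.11). Each of these 12 genes was called without any one of the 8 arrays, and Abra (-2.08, adjusted p = 0.0674) and Sele (-2.02, adjusted p = 0.0541) lost the call with the hybridization covariate.

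Fam111a lay at 11.1 to 11.2 log2 in the 4 doxorubicin hearts and at 4.30, 7.66, 4.46 and 4.35 log2 in control hearts 1 to 4, so control 2 stood between the groups. Without control 2 the log2 difference was 6.83. Pxmp4, a peroxisomal membrane protein gene, rose 5.17-fold (2.37, SE 0.13), and its second probe set rose by 1.39. The secretin receptor gene Sctr rose by 1.44 (SE 0.19) and Gramd2b by 1.36 (SE 0.27), with its other probe sets at 0.50 and 1.41. Idi1, an enzyme of isoprenoid and sterol synthesis, rose by 1.08 (SE 0.15), and the actin-nucleating muscle gene Lmod3 by 1.03 (SE 0.09), while the second probe sets of Idi1 (0.44) and Lmod3 (0.21) did not pass. Ogn, a matrix proteoglycan, rose by 1.01 (SE 0.21), although its other probe sets ranged from -0.33 to 1.09. Smaller rises were seen for Pdpr, a regulator of pyruvate dehydrogenase phosphatase (0.97, SE 0.12), Drg1 (0.94, SE 0.16), the dynein gene Dnah7 (0.91, SE 0.12), Qsox1 (0.89, SE 0.17) and Tm6sf1 (0.87, SE 0.18). Gramd2b, Ogn and Tm6sf1 lost the call without most single arrays, with adjusted p up to 0.108, 0.127 and 0.119, and Qsox1 and Drg1 without 4 of the 8, up to 0.0923 and 0.0655. With the hybridization covariate Pxmp4 and Dnah7 alone of these 12 kept the call. Of those that lost it, Fam111a (5.04, adjusted p = 0.185), Lmod3 (0.98) and Gramd2b (0.70) had smaller differences than without it, and Sctr (1.56), Ogn (1.31), Tm6sf1 (1.15), Idi1 (1.13), Pdpr (1.05), Qsox1 (1.01) and Drg1 (0.96) larger ones.

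**Figure D1:**
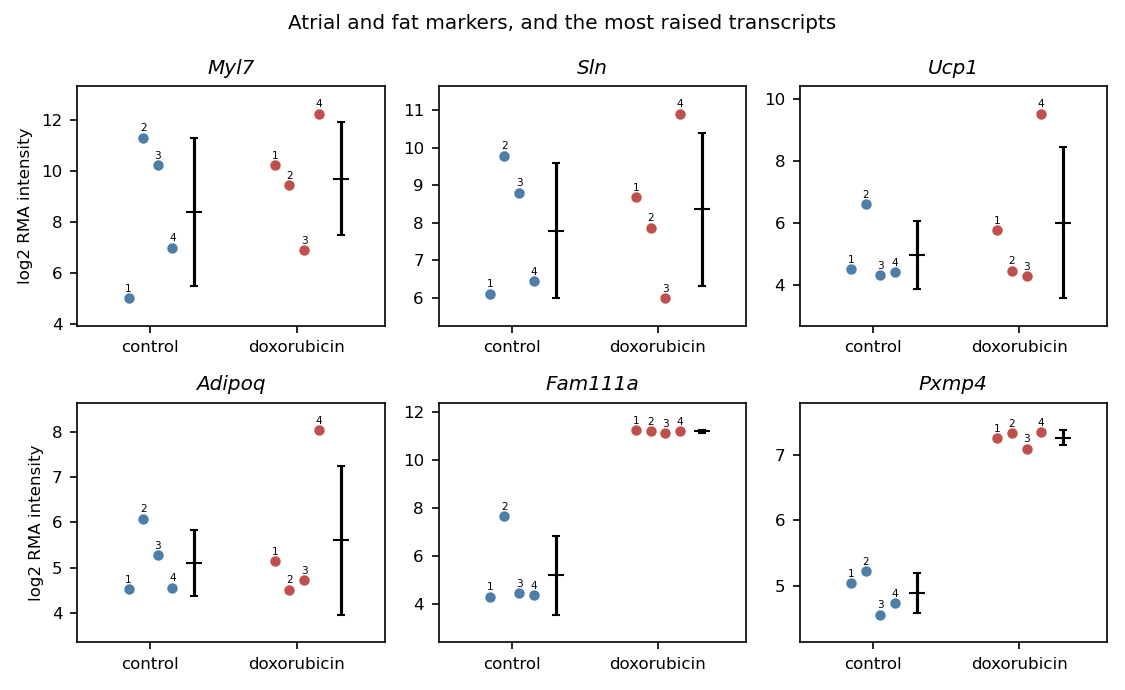
Log2 RMA intensity (vertical axes) of 4 atrial and fat markers and of Fam111a and Pxmp4 in the 4 control and 4 doxorubicin hearts. Each point is 1 array with its replicate number, and the bar beside the points is the mean ± SD of the 4 arrays. Myl7 spans 5.03 to 12.3 over the arrays with overlap of the groups, while Fam111a is 11.1 to 11.2 in every doxorubicin heart and 7.66 in control 2.

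Immediate early genes had the lowest median of the 39 lists. Of 35 measured, 22 fell, none rose (1 higher at an unadjusted p under 0.05) and 13 did not pass, with a median difference of -0.79. Adjusted over the list alone, 29 fell and 1 rose. Besides Nr4a3 and Atf3, falls were seen for Ier5 (-1.61, SE 0.11; other probe sets -0.83 and -0.27), for Ier3 (-1.40, SE 0.09), for Zfp36, which destabilizes cytokine mRNA (-1.42, SE 0.11), and for the matricellular growth factor gene Ccn2 (-1.28, SE 0.08). Jun (-1.67), Dusp1 (-1.54), Myc (-0.97) and Egr1 (-0.80) also fell. Fos stood at -0.50 and Nr4a1 at -0.38 without passing. The camera test called the list lower (adjusted p = 1.29e-33), and the call held with an estimated correlation (adjusted p = 0.0369). With the hybridization covariate 9 of the 22 stayed called.

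**Figure D2:**
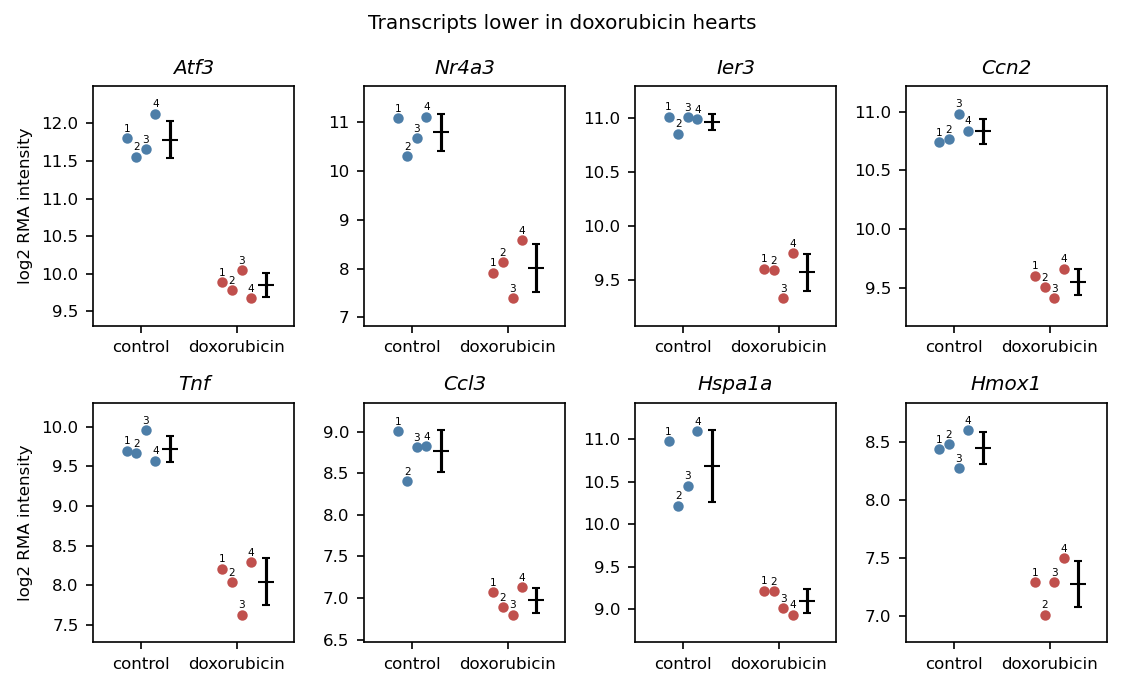
Log2 RMA intensity (vertical axes) of 8 transcripts in 4 control and 4 doxorubicin hearts. Each point is 1 array with its replicate number, and the bar beside the points is the mean ± SD of the 4 arrays. In each panel the 4 doxorubicin hearts lie below the 4 control hearts, as for Atf3 with means of 9.85 and 11.8.

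Of 30 NF-kB targets and cytokine genes measured, 28 had negative differences, and 14 fell, none rose (none higher unadjusted) and 16 did not pass, and adjusted over the list alone 20 fell. Beside Sele and Ccl3 these were led by the cytokine gene Tnf (-1.68, SE 0.14) and the chemokine gene Ccl4 (-1.46, SE 0.14). Il1a (-1.27) and the NF-kB inhibitor gene Nfkbia (-0.82) fell as well, while Il6 (-0.33), Il1b (-0.33) and Ptgs2 (-0.39) did not pass. The list median was -0.64 and camera called it lower (adjusted p = 1.13e-22). That call was lost with an estimated correlation (adjusted p = 0.244), while fry called the list lower (adjusted p = 0.00662). The count was 9 without doxorubicin 2 or doxorubicin 3, and 2 with the hybridization covariate. No macrophage marker passed by its representative probe set in the same hearts, and their median was 0.17. A second probe set of the macrophage marker Laptm5 rose, by 0.48.

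Markers of load and hypertrophy, which rise in stretched or growing heart muscle, were lower in part. Of 15 measured, 5 fell and 10 did not pass, and adjusted over the list alone 7 fell. They were Xirp1, the growth factor gene Hbegf (-1.29, SE 0.09), Ccn2, the natriuretic peptide gene Nppb (-1.01) and the calcineurin regulator Rcan1 (-0.96, SE 0.16). Rcan1 lost the call without doxorubicin 3 (adjusted p = 0.0525). The list median was -0.25 and camera called it lower (adjusted p = 1.10e-08). That call was lost with an estimated correlation (adjusted p = 0.244), while fry called the list lower (adjusted p = 0.00662). Nppa stood at 0.56 (SE 0.72). It is also in the atrial list and spanned 10.7-fold over the single hearts, so its value says little about load. Myh7 stood at -0.06, and with the hybridization covariate 3 of the 5 stayed called.

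Of 29 heat shock genes measured, 6 fell and 23 did not pass, the same 6 by number adjusted over the list alone. Since lower stress genes were a reported theme of these samples, this count is not independent evidence of direction. The inducible chaperone gene Hspa1a fell by 1.59 (SE 0.18), which is uncertain because a near-identical gene, Hspa1b, can bind the same probes. The co-chaperone gene Dnajb1 fell by 1.44 (SE 0.12), the small heat shock gene Hspb1 by 0.78 (SE 0.10) and Bag3 by 0.34 (SE 0.06). Bag3 lost the call without any one of 6 arrays (adjusted p up to 0.0821). The median of the list was 0.07 while its mean was -0.11 and camera, which did not call it, gave a lower direction (adjusted p = 0.385). The count was 3 without any one array of control 1, control 3, control 4, doxorubicin 1, doxorubicin 2 and doxorubicin 4, and 1 with the hybridization covariate.

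Other stress pathways showed falls in a few regulators. In the list for endoplasmic reticulum stress and the integrated stress response, 4 of 24 fell, and adjusted over the list alone 5 fell and 2 rose. They were the transcription factors Ddit3 (-0.95, SE 0.08) and Atf4 (-0.53, SE 0.07), the pseudokinase gene Trib3 (-0.83, SE 0.10) and the glutathione-degrading enzyme gene Chac1 (-1.05, SE 0.16). The list median was 0.07, its mean -0.04, and camera did not call it (adjusted p = 0.996, direction lower). Among 25 antioxidant genes, heme oxygenase Hmox1 fell by 1.17 (SE 0.11) and Gclc, which makes the first step of glutathione synthesis, by 1.05 (SE 0.09). Adjusted over the list alone 3 fell, the median was -0.03 and the list was not called (adjusted p = 0.0888), but it was called lower without control 4, doxorubicin 1 or doxorubicin 4 (adjusted p 0.0112 to 0.0432) and with the filter on dim probe sets (adjusted p = 0.0384). Nfe2l2, the regulator that gives the list its name, stood at -0.25 (SE 0.06, adjusted p = 0.0831), and Mt2A at -0.48 (SE 0.15).

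Some targets of p53, the transcription factor activated by DNA damage, fell, and none was called higher over all probe sets. Of 20 measured, 5 fell, and adjusted over the list alone 6 fell and 2 rose. Cdkn1a (0.03), Aen (0.30), Ei24 (0.24) and Bbc3 (-0.27) did not pass over all probe sets. Plk2, a kinase gene, fell by 1.39 (SE 0.15), the growth-arrest gene Gadd45a by 1.11 (SE 0.09), the p53 ubiquitin ligase gene Mdm2 by 0.70, Sesn2 by 0.60 (SE 0.12) and the phosphatase gene Ppm1d by 0.52 (SE 0.10). The list was not called by camera (median -0.04, adjusted p = 0.0888) and was called by fry (adjusted p = 0.00662). Without doxorubicin 1 camera called it (adjusted p = 0.0432). The number that fell was 2 without doxorubicin 1 or doxorubicin 3, 3 without any one of the other arrays, and 1 with the hybridization covariate. Sesn2 and Ppm1d lost the call without 5 and 6 of the 8 arrays, with adjusted p up to 0.0907 and 0.103, and a dim second Sesn2 probe set stood at -0.05.

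**Figure D3:**
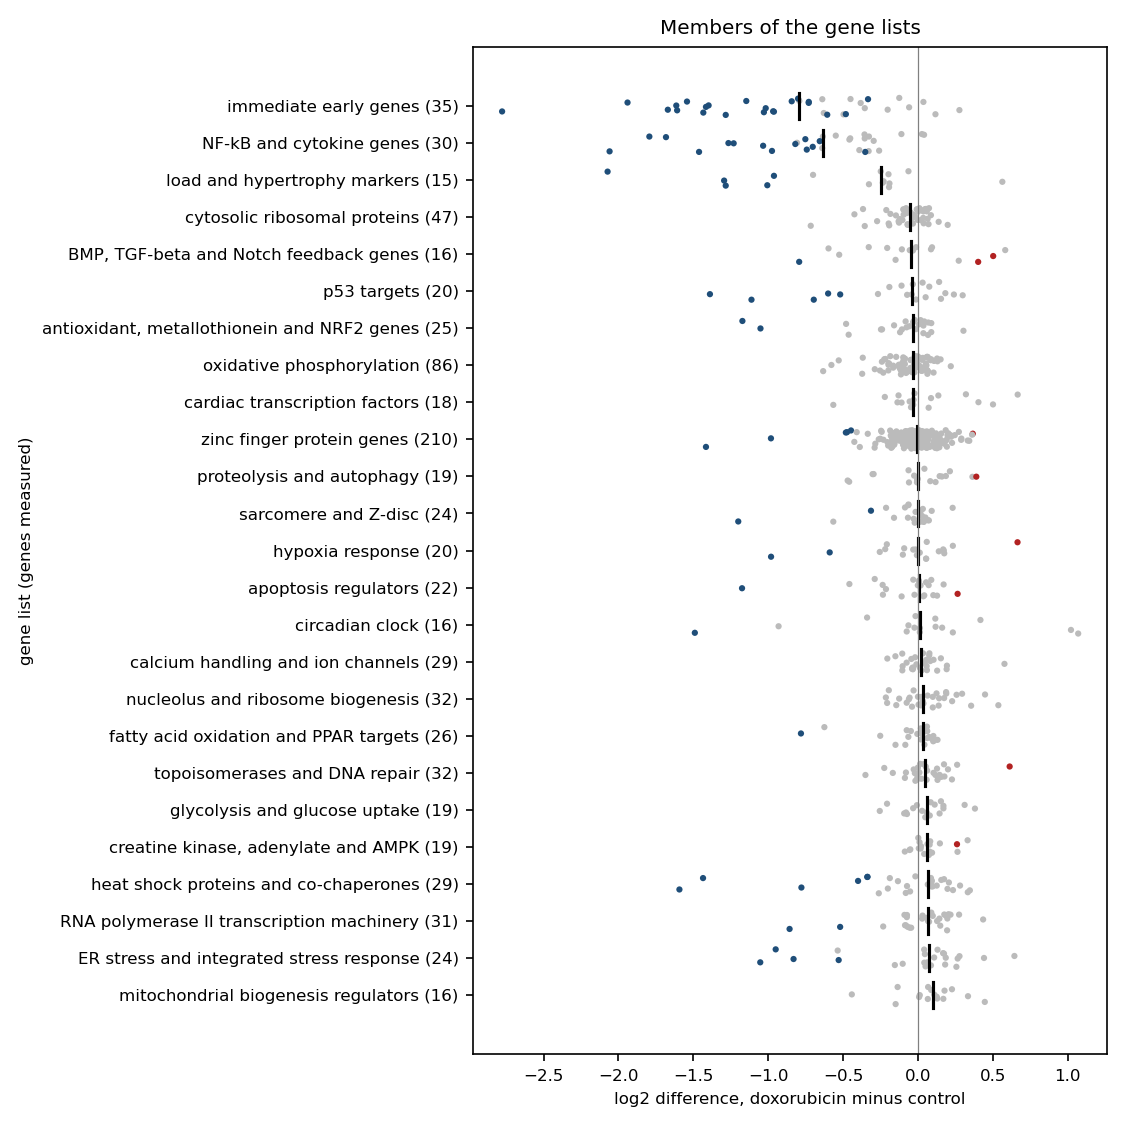
Log2 difference, doxorubicin minus control (horizontal axis), of each measured member of the 25 pathway lists (vertical axis, with the number of genes measured). Blue points fell and red points rose at a limma adjusted p under 0.05, grey points did not pass, and black bars are list medians. Immediate early genes have the lowest median, -0.79, and most other medians lie near 0.

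The lists for energy metabolism and contraction held few called genes. Muscle genes outside these lists did change, such as Klhl40 (-3.33), Abra (-2.22) and Lmod3 (1.03). Of 86 oxidative phosphorylation genes none passed in limma, with 3 higher and 1 lower at an unadjusted p under 0.05, a median of -0.03 and camera adjusted p = 0.32. Cox5a stood at -0.15 (SE 0.05) and Ndufaf4 at 0.15 (SE 0.06). None of 16 mitochondrial biogenesis regulators passed (4 higher and 1 lower unadjusted, median 0.10, adjusted p = 0.189), with Twnk at 0.33 and Ppargc1b at -0.44. Of 26 fatty acid oxidation genes, the pyruvate dehydrogenase kinase gene Pdk4 fell by 0.78 (SE 0.11), and adjusted over the list alone 2 fell (median 0.04, mean -0.04, adjusted p = 0.996, direction lower). No glycolysis gene passed of 19 (4 higher and 1 lower unadjusted, median 0.06, adjusted p = 0.32), with Gpi at 0.17. Among 19 genes of creatine kinase, adenylate and AMPK function, Ak3 rose by 0.26 (SE 0.06), and adjusted over the list alone 2 rose (median 0.06, adjusted p = 0.187). Ak3 lost the call without any one of the 8 arrays (adjusted p up to 0.129).

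Of 24 sarcomere and Z-disc genes, the Z-disc genes Myot (-1.20, SE 0.14) and Csrp3 (-0.31, SE 0.05) fell, and adjusted over the list alone 3 fell and 1 rose (median -0.0017, adjusted p = 0.363). Calcium handling and ion channel genes had none of 29 past the test (2 higher and 1 lower unadjusted, median 0.02, adjusted p = 0.898), with Gja1 at -0.20 and Ryr2 at 0.15. None of 18 cardiac transcription factor genes passed (3 higher and 2 lower unadjusted), though 1 fell adjusted over the list alone. Their median was -0.03, their mean 0.04 and camera adjusted p = 0.962, direction lower, with Tbx5 at 0.67 (SE 0.24) and Myocd at -0.57 (SE 0.13). In the proteolysis and autophagy list Trim54, a muscle ubiquitin ligase gene, rose by 0.39 (SE 0.06), 1 of 19, and adjusted over the list alone 1 rose and 3 fell. Its median was -0.0020, its mean 5.20e-04 and camera adjusted p = 0.779, direction higher.

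Among 22 apoptosis regulators the pro-apoptotic gene Bcl2l11 fell by 1.17 (SE 0.08), although its other probe sets stood at -0.13 and -0.06, and Casp9 rose by 0.26 (SE 0.06). Casp8 stood at -0.46 (SE 0.10, adjusted p = 0.0541) without passing, while its second probe set fell by 0.64. Adjusted over the list alone 2 fell and 1 rose (median 0.0069, mean -0.08, adjusted p = 0.508, direction lower). Casp9 lost the call without any one of the 8 arrays (adjusted p up to 0.119), and its other probe sets stood at 0.11 and near 0. Of 20 hypoxia-response genes, Ddit4 (-0.98, SE 0.10) and Vegfa (-0.59, SE 0.12) fell and the vasodilator peptide gene Adm rose (0.66, SE 0.10), with the same numbers adjusted over the list alone (median 0.0025, mean -0.04, adjusted p = 0.903, direction lower). Vegfa lost the call without any one of 6 arrays (adjusted p up to 0.104). In the list of topoisomerases and DNA repair, 1 of 32 passed, the double-strand break gene Nbn, which rose by 0.61 (SE 0.12) and lost the call without any one of 7 arrays (adjusted p up to 0.122). Adjusted over the list alone 1 rose and 1 fell (median 0.05, adjusted p = 0.32), and Top1 stood at -0.35 (SE 0.09, adjusted p = 0.0881).

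Of 31 genes of the RNA polymerase II machinery, Polr2a, the largest subunit of the enzyme, fell by 0.86 (SE 0.11) and Hexim1, an inhibitor of the elongation factor P-TEFb, by 0.52 (SE 0.08), the same number adjusted over the list alone (median 0.07, adjusted p = 0.322, direction higher). None of 47 cytosolic ribosomal protein genes passed (1 higher and 2 lower unadjusted, median -0.05, adjusted p = 0.187), and none of 32 nucleolar genes did (10 higher and 2 lower unadjusted, median 0.03, adjusted p = 0.187). Rps28 stood at -0.72 (SE 0.31) and Polr1a at 0.29 (SE 0.08). The ribosomal protein list was called lower without control 4 (adjusted p = 0.0367) and without doxorubicin 1 (adjusted p = 0.0432). Of 210 zinc finger protein genes 5 fell and 1 rose, and adjusted over the list alone 7 fell and 2 rose (median -0.0081, adjusted p = 0.32), with Zfp521 at -0.98 (SE 0.17) and Zfp217 at -0.45 (SE 0.06). Zfp521 lost the call without control 3 (adjusted p = 0.0563).

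Of 16 circadian clock genes, the repressor gene Nfil3 fell by 1.49 (SE 0.28), also adjusted over the list alone, and lost the call without control 2, doxorubicin 1, doxorubicin 3 or doxorubicin 4 (adjusted p up to 0.0946). The list was not called by camera (median 0.01, adjusted p = 0.996). Its members went both ways, and camera looks for a shared direction, so it could not show opposite changes. Bmal1 (-0.93, SE 0.50), Dbp (1.07, SE 0.64) and Bhlhe41 (1.02, SE 0.36) did not pass. With the replicate number as a block in limma, Bmal1 and Dbp passed (adjusted p = 0.00806 for Bmal1 and 0.0473 for Dbp). Whether the numbers pair the hearts is not given in the sources used here. In the list of 16 feedback genes of BMP, TGF-beta and Notch signalling, Id4 fell by 0.79 (SE 0.15; other probe sets -0.49 to -0.36, not past the test), Id1 rose by 0.50 (SE 0.10) and Bambi rose by 0.40 (SE 0.08), and adjusted over the list alone 3 fell and 3 rose. Its median was -0.04 (adjusted p = 0.508). The 3 calls were each lost without 4 to 7 of the single arrays, with adjusted p up to 0.0854, 0.112 and 0.116.

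Few markers of cell types changed. The lymphocyte list was called higher (median 0.11, adjusted p = 0.0425), a call lost with an estimated correlation (adjusted p = 0.739), and without control 2, control 3, doxorubicin 2 or doxorubicin 3 (adjusted p 0.0753 to 0.208). Of its 13 genes, the cytotoxic granule gene Gzmb rose by 0.78 (SE 0.11) from 4.32 to 5.10 log2, its dimmer second probe set stood at 0.38 without passing, and adjusted over the list alone 2 rose. Among 12 endothelial markers Tie1 rose by 0.34 (SE 0.06), also adjusted over the list alone, and lost the call without doxorubicin 1, 2 or 3 (adjusted p up to 0.0576). The endothelial median was 0.07 and camera adjusted p = 0.75. No representative probe set was called by limma among 15 macrophage markers (3 higher and 2 lower unadjusted, median 0.17, adjusted p = 0.32), 14 fibroblast and matrix genes (1 higher unadjusted, median 0.18, adjusted p = 0.31) or 13 smooth muscle and pericyte markers (3 higher and 2 lower unadjusted, median -0.08, adjusted p = 0.779). Fibroblast genes were called higher without control 3 (adjusted p = 0.0243) and with the hybridization covariate (adjusted p = 0.00978). Cd14 stood at -0.53 (SE 0.16) and Col3a1 at 0.40 (SE 0.20). The representative probe set of the pericyte channel gene Abcc9 stood at 0.22, while 2 others rose, by 0.69 and 1.42.

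The remaining marker lists had no call by camera and no member called by its representative probe set, also when adjusted over the list alone. Median and adjusted p were 0.0099 and 0.934 for neutrophils (7 genes, 1 higher unadjusted), -0.07 and 0.363 for red blood cells (7 genes, 1 lower unadjusted), and 0.0054 and 0.996 for mast cells (9 genes, none unadjusted). They were -0.02 and 0.521 for nerve and glial cells (8 genes, 1 lower unadjusted), -0.0034 and 0.996 for mesothelium (6 genes, none unadjusted, direction higher) and -0.05 and 0.648 for skeletal muscle (12 genes, none unadjusted). One of the other probe sets of the skeletal muscle gene Myh1 fell by 1.26, against 0.30 for its representative. Ventricular markers had a median of -0.02 and a mean of 0.04 (7 genes, 1 higher unadjusted, adjusted p = 0.75, direction higher), with Myl2 at -0.02 and Myl3 at 0.03. For 9 adipocyte genes the median was 0.36 (none unadjusted, adjusted p = 0.476), and for 7 atrial genes 0.56 (none unadjusted, adjusted p = 0.563).

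Atrial and fat markers differed between single hearts far more than between groups. The atrial light chain gene Myl7 ranged from 5.03 log2 in control 1 to 12.3 log2 in doxorubicin 4, a 150-fold span, with group means of 8.40 ± 2.90 and 9.72 ± 2.22 log2 (SD, n = 4; exact permutation p = 0.457). Myl4 spanned 88.0-fold and the atrial calcium pump regulator Sln 30.3-fold. Doxorubicin 4 held 9.54 log2 of Ucp1, the uncoupling protein of brown fat, and 8.04 log2 of the fat hormone gene Adipoq, against highest values of 6.62 and 6.08 log2 in the control hearts.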

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

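The tests of the Fam111a values below were chosen before their results were seen, though after the gene had stood out. Among 170 groups of 4 arrays, 7 had 1 array far from the other 3, against 8.5 expected by chance. The gap to the nearest other array, as a share of the whole range of the group, is given for each and exceeded Dixon's 95% critical value.

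Fam111a was 7.66 log2 in control 2 and 4.30 to 4.46 log2 in the other control hearts, a gap of 0.952 of the range. Control 2 lay 3.21 log2 above the next control heart, and the difference was 6.83 log2 without control 2. RNA of a doxorubicin heart mixed into control 2 is a candidate explanation: by Fam111a the share would be 7.84%, and over 213 other probe sets called higher control 2 showed a median 15.98% of the group difference (bootstrap interval 10.9 to 20.1), against -8.32%, -3.09% and -9.05% in control hearts 1, 3 and 4. The interval is over probe sets, not hearts, and the Fam111a share lies below it. Control hearts 1, 3 and 4 were each set against a mean that includes control 2, which can lower their shares. Over the 473 lower probe sets the share of control 2 was 4.72%, under the 9.22% of control 3, so mixing and a difference of control heart 2 itself cannot be told apart. Rats of different origin also stay open, because 1 of 18 RT1 genes was called against 421 of 14199 others (Fisher's exact test, one-sided p = 0.419), too few genes to decide, and an effect of doxorubicin on the gene remains among the open explanations.

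Ier3 was 10.85 log2 in control 2 and 10.99 to 11.01 log2 in the other control hearts (gap 0.839). Mustn1 was 6.65 log2 in doxorubicin 4 and 6.47 to 6.50 log2 in the other doxorubicin hearts (gap 0.857). Irs2 stood at 6.44 log2 in doxorubicin 1 and at 6.26 to 6.29 log2 in the rest (gap 0.834). Lmod3 reached 7.24 log2 in doxorubicin 3, with the others at 6.95 to 6.98 log2 (gap 0.905). Zfp521 was 5.29 log2 in doxorubicin 3 and 5.81 to 5.88 log2 in the others (gap 0.883). The hybridization control level was 10.13 log2 on array doxorubicin 1 and 9.97 to 9.99 log2 on the other doxorubicin arrays (gap 0.848).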

How the results depend on the processing

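The covariates for the hybridization control level and the atrial marker level were chosen after seeing the data, and all other alternatives before. Under repeated quantile normalization, median centring, the filter on dim probe sets, an intensity trend, a robust fit, array weights, adjustment over genes alone, the offset, the replicate block, both covariates and each left-out array, all of the 422 called genes that were tested kept their sign, and with the mean of probe sets 421 did. In most of these settings the sign could not change. The filter, the trend, the robust fit, adjustment over genes alone and the replicate block leave the differences as they are. All 687 called probe sets had groups that did not overlap, so array weights, the offset or a left-out array could not reverse a sign. Genes called numbered 395 to 555 in all settings listed here, the replicate block, left-out arrays and the hybridization covariate aside. Immediate early genes, NF-kB genes and load markers were called lower by camera in each of them, and no named gene or list that was called changed direction in them. Array weights gave 350 probe sets and 186 genes higher (65.0% of genes lower), for which the cause was not tested.

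The lymphocyte list lost its call with the filter on dim probe sets (adjusted p = 0.191), the mean of probe sets (0.0610), the offset of 16 (0.0892), an estimated correlation (0.739) and fry (0.113), and the cause was not tested. With an estimated correlation 1 list was called, and NF-kB genes and load markers each had adjusted p = 0.244. With fry 4 lists were called. These were immediate early genes (adjusted p = 2.65e-04), and NF-kB genes, load markers and p53 targets (each adjusted p = 0.00662).

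With 7 arrays, probe sets changed ranged from 397 (without doxorubicin 1) to 854 (without control 2), those higher from 76 to 395, genes changed from 248 to 512, genes higher from 44 to 215 and genes lower from 204 to 305. NF-kB genes lower numbered 9 to 15, heat shock genes 3 to 6 and p53 targets 2 to 3. Lists called numbered 3 to 7, and the lymphocyte adjusted p ran from 0.00180 (without control 1) to 0.208 (without control 2). Fewer arrays leave fewer degrees of freedom. Without control 2, which stood between the groups, 58.0% of called genes were lower, against 73.0% with all arrays. Of 70 named genes that were called, 50 stayed called without each array.

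The hybridization covariate left 92 probe sets (8 higher, 84 lower), 60 genes (3 higher, 57 lower), the same 60 at 1.5-fold, and 19 changed members over all lists. Lower were 9 immediate early genes, 2 NF-kB genes, 3 load markers, 1 heat shock gene and 1 p53 target, and the lymphocyte adjusted p was 0.212. Of the 60, 59 were among the 422. Standard errors over all genes were 1.73 times as large in the median, since the covariate differs between the groups, while the median difference of called immediate early genes went from -1.09 to -1.07. Over the 422 called genes the median ratio of the difference with the covariate to that without it was 1.0025, and single genes that lost the call went both ways, as Ogn from 1.01 to 1.31 and Gramd2b from 1.36 to 0.70.

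Over all probe sets the replicate numbers did not pair the hearts. Same-numbered hearts had correlations of 0.06, -0.04, -0.03 and -0.18 between deviations from their group means, across probe sets. No control heart correlated best with the doxorubicin heart of its own number. With the replicate block 121 probe sets and 60 genes were higher, and 305 genes were called (80.3% lower), 272 of them shared. Of the named genes, 16 were called only without the block, among them Chac1 (adjusted p = 0.0522 with it), Trim54 (0.0600) and Csrp3 (0.0648). Another 2, Bmal1 (adjusted p = 0.00806) and Dbp (adjusted p = 0.0473), were called only with it. Over 16 clock genes same-numbered hearts did deviate together (0.72, 0.87, 0.47 and 0.77), and whether the numbers mark a shared day or time of day is not given in the sources used here. Low signal limits what can be said of dim genes, since detection calls were not used here.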

Other observations

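The test of the array normalization and the hybridization covariate, the class of histone probe sets and the tests of clock genes were chosen only after the result was seen. A few histone probe sets fell steeply. Of 34, 4 fell in limma, and the median was -0.01. H4cl1 fell by 3.02, and 3 probe sets that match several histone genes fell by 1.81, 1.27 and 0.85. The one that fell by 1.27 lists the same 5 histone H4 genes as 2 brighter probe sets, which stood at -0.21 and -0.08 without passing. The single-gene probe set of the variant H2az1 stood at 0.30 (SE 0.07, adjusted p = 0.0557) and that of H2ax at -0.22 (SE 0.09).

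Clock genes were looked at for their spread between hearts of one group, after their values were seen. The within-group SD was 1.14 log2 for Dbp, 0.90 for Bmal1, 0.64 for Bhlhe41, 0.49 for Nr1d1 and 0.48 for Per2, above 98.6% to 99.8% of the 9365 brighter genes, whose median was 0.14, and 0.16 for Per3. Bmal1 was 8.29, 8.46, 7.53 and 6.75 log2 in control hearts 1 to 4 and 7.70, 7.53, 6.54 and 5.54 log2 in doxorubicin hearts 1 to 4. Dbp was 5.66, 5.68, 6.53 and 7.88 log2 in the control hearts and 6.80, 6.16, 8.28 and 8.79 log2 in the doxorubicin hearts. Over 16 clock genes the deviations of same-numbered hearts from their group means correlated at 0.72, 0.87, 0.47 and 0.77. Their mean, 0.706, was the highest of the 24 ways of pairing the hearts (exact p = 0.0417, the smallest possible), and another pairing reached 0.686. Without Dbp and Bmal1 the numbered pairing was again the highest (0.599, exact p = 0.0417).

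Only the real split of the 8 arrays, 1 of 35, gave as many changed probe sets. It gave 687, and the highest other split gave 1. A share of 1 of 35 is the smallest possible, so chance is unlikely for this count but not excluded. Each other split mixes hearts of both groups, so any difference between the groups, not doxorubicin alone, would make the real split stand out. The fall of immediate early genes could come from cells other than muscle, from array processing or from doxorubicin. The 15 macrophage markers did not show fewer macrophages, with a median of 0.173 and an upper quartile of 0.196. At an unadjusted p under 0.05, 3 were higher and 2 lower, the latter Cd14 (-0.53) and Adgre1 (-0.24). Their mean level differed by 0.081 between the groups (exact permutation p = 0.514) and was highest in doxorubicin 4 (0.253). Among 24 probe sets for Bacillus RNA spikes the lowest difference was -0.050, while the list stood at -0.79. All 18 hybridization control probe sets were lower, with a mean difference of -0.30. The list stayed called under repeated quantile normalization and median centring. The arrays had already been normalized together, which takes out a shift of whole arrays. The spikes and these scalings could therefore show little and decide nothing. With the hybridization control level as a covariate, 100% of the 22 called genes kept a fall at least 0.5 times as large. The median difference of the 22 went from -1.09 to -1.07 and the median SE from 0.12 to 0.20, and 9 stayed called. The control levels of the groups did not overlap, at 10.21 to 10.57 log2 on control and 9.97 to 10.13 log2 on doxorubicin arrays. A technical shift shared by a whole group would therefore stay in the group difference. The fit speaks only to a trend that also runs within the groups. A hybridization day shared by a whole group is not given in the sources used here and stays open beside an effect of doxorubicin, and hearts that were never perfused are not analysed here.

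Called genes fell more often than they rose, and loss of short-lived transcripts is one hypothesis for it. Zinc finger protein genes, a class known for short-lived transcripts, had a median of -0.0081 log2, at percentile 48.96 of 10000 random lists matched on intensity, whose middle range was -0.02 to 0.01. Members went both ways, so this median decides nothing, and the hypothesis stays open.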
